A study of Pimephales promelas with 12 samples.

How the data were processed

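Total RNA from the livers of male fathead minnows was hybridised to 12 two-colour Agilent oligonucleotide arrays, with liver RNA in Cy5 and a reference pool of liver, gonad and brain RNA from both sexes in Cy3, per the labels' protocols. There were 4 arrays for the solvent control, 4 for EE2 and 4 for the mixture of EE2 and ZM. The series' design text calls them biological replicates. Whether each array holds 1 fish is not given in the sources used here.

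Each deposited scanner file holds, per the file headers, the mean intensity of each spot and the median intensity of its local background in both channels, with flags for saturation, outliers and signal well above background. Feature Extraction 9.5 made these files, per the submitters' processing notes. The same files hold a processed log10 ratio of Cy5 over Cy3, background-subtracted and dye-normalised within the array, per the file headers. The deposited series matrix holds values that differ by at most 0.005 from that log10 ratio on every array, so its scale, direction and spot order are known, and its median is 0 on each of the 12 arrays.

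Each array held 44407 spots, of which 1417 were controls, and 21495 probes of 60 bases with 2 spots each. The starting values were the mean intensities, corrected with limma's normexp (version 3.58.1 in R 4.3.3) with an offset of 50 on the median local background. Loess normalisation within each array followed, with control spots at weight 0 and no step between arrays. Control spots and spots with an outlier flag were left out, and the spots of a probe were averaged. A probe was tested if its Cy5 signal was well above background on at least 3 of the 4 arrays of at least 1 group, which left 12591 probes. Levels are log2 ratios of Cy5 over Cy3, and saturated spots were kept at their value.

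One model (lmFit and eBayes) with a mean per group was fitted to all 12 arrays, and the 3 differences between groups were tested with Benjamini-Hochberg adjustment at 0.05 over all tested probes. Confidence intervals are at 95%, from the same fit. Single genes were also compared with exact two-sided permutation tests of 4 against 4 arrays, whose smallest possible p is 0.0286. These permutation p-values are not adjusted for the number of genes, and the limma adjusted p is given beside them. The retained response used the 100 probes with the smallest p in each split where fewer than 100 passed an adjusted p of 0.05 and a 2-fold change.

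Gene names come only from the arrays' own annotation. Of 21495 probe names, 33 are gene names and the others are names of expressed sequence contigs, and 0 were found among the identifiers of the RefSeq table for the species. No genome was used here, so probe positions are not given. The rule for named genes was fixed before the data were examined. It takes named probes that pass the test without overlap between groups, or else the 5 smallest p in each direction, up to 4 called members of each gene list, and always vitellogenin, egg envelope and estrogen receptor genes, cyp1a and cyp19a1. Because 11 named genes were tested, all of them are named, with no difference between groups for complement C3S, whose spots were saturated on all 12 arrays. The 4 unnamed probes printed by identifier are the 1 changed probe and 3 chosen after their values were seen. Of 25 gene lists fixed before the data were examined, 7 had 1 tested member each and 18 had none. A set test was planned only for lists with at least 4 tested genes, so camera and fry were not run.

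The 7 lists with a tested member were nuclear estrogen receptors (estrogen receptor alpha), egg envelope proteins and gonad germ cell markers (both zona pellucida glycoprotein 3), complement, coagulation and acute phase (complement C3S), cell cycle (cyclin B1), leukocyte markers (CD18 type 2) and exocrine pancreas markers (alpha amylase). Adjusted over the list alone, 1 of these genes, estrogen receptor alpha, passed in EE2 against control and in the mixture against control, and 0 passed in the mixture against EE2. With 1 tested member per list, that p is the unadjusted limma p, with no correction over the lists or the comparisons.

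On mixture replicate 3, a few spots with a very high local background distorted the normexp correction of the whole array. Controls 1 and 2 and mixture 1 were distorted to a smaller degree, with a 10th percentile of corrected Cy5 signal of 109, 153 and 81.4, against 71.0, 70.1 and 69.5 after repair. A repair that sets any local background above 2 times the array's median to that median was added, and both the repair and its threshold were chosen after seeing the data. The planned correction remains the basis of the report, and the repaired values are given beside it where they change a call of a printed probe and for some named genes. Other alternatives were the deposited processed log ratios and series matrix, no background subtraction, an offset of 10, median centring, Aquantile, Cy5 alone, 3 other probe filters, only the 2 groups compared, eBayes with trend and robust, array weights, slide or replicate number as a block, and each array left out in turn. Maximum likelihood normexp, and the repair combined with array weights, with the replicate number or without EE2 replicate 2, and the processed log ratios with slide as a block, were added after seeing the data. Between alternatives, a change of sign was counted only where 1 of the 2 values was larger than its standard error.

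Precision can be read from the spots and arrays. Duplicate spots differed with a median SD of 0.051 to 0.080 per array, for log2 ratios of the mean intensities without background correction or loess. The median residual SD between arrays of a group was 0.325, or 0.276 with the repair, for corrected and normalised ratios. The duplicate and residual values are therefore not directly comparable. Arrays correlated across probes with r between 0.806 and 0.941, or between 0.880 and 0.941 with the repair. The fit was tested on simulated data with the repaired spread for EE2 against control. Of 100 changes of 1 on the log2 scale among 12591 probes it called 56%, of 100 changes of 2 it called 90%, with 12 false calls and none with the wrong sign. The planned setting has a wider spread, and the share called also depends on how many probes change. These shares may therefore be too high for the planned setting. Simulated retained shares of 1, 0.5 and 0 were returned as 1.00, 0.495 and 0.002. That simulation changed many probes by more than the median effect measured here, with independent noise per probe. It therefore does not show how the estimate behaves at the size of effect in these data.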

Results

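Gene expression was measured in the liver of male fathead minnows, a small freshwater fish used in toxicity testing, after exposure to a solvent control, to EE2 (ethinylestradiol, a synthetic estrogen) or to EE2 together with the anti-estrogen ZM. Each of the 3 groups held 4 arrays. Liver RNA carried Cy5 and a pooled reference from liver, gonad and brain of both sexes carried Cy3, so every level below is a log2 ratio of liver over reference, and the reference drops out of differences between groups. The labels give neither doses nor exposure times, and no group received ZM alone. Between 56.7% and 64.1% of the spots on an array had a Cy5 signal well above background, and 69.1% to 74.0% had a Cy3 signal well above background. After probes with dim liver signal were left out, 12591 of 21495 probes were tested. Only 33 probes carry a gene name in the files, of which 11 were tested. No probe carries the name of vitellogenin, cyp1a or cyp19a1, so no probe can be given for these genes of the estrogen and dioxin responses, though unnamed probes may measure them. Precision is limited by the number of arrays.

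The first comparison, EE2 against control, asks what the estrogen alone did to the male liver. Estrogen receptor alpha, the nuclear receptor that binds estrogen and switches on egg yolk genes in fish liver, had the largest difference among the named genes. Its log2 ratio was 2.84 ± 1.48 (SD, n = 4) after EE2 and -0.43 ± 0.18 (SD, n = 4) in controls, a 9.68-fold higher level (95% confidence interval 4.23 to 22.2). That interval rests on a spread shared by the 3 groups. The EE2 arrays spread far more than the others, so it may be too narrow. All 4 EE2 arrays lay above all 4 control arrays (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). The receptor was also higher on the EE2 array of each of the 4 slides, by 1.05 to 4.31 on the log2 scale. In limma's test the adjusted p was 0.0954 over all probes, which does not pass 0.05. Over the list alone it was 6.8e-05, an unadjusted p because that list of nuclear estrogen receptors has 1 tested member. Its probe (EA_Pp_62566) has the sequence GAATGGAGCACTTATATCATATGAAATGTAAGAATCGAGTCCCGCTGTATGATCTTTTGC. Estrogen receptor beta, the other named member of that list, was not well above background on any of the 12 arrays. EE2 replicate 2 had a receptor level of 0.64 against 3.29 to 3.72 on the other EE2 arrays, and without it the receptor's difference was 4.01. The adjusted p of 3.9e-06 in that fit is no independent test, because the array was left out for its receptor level.

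None of the other named genes passed the test in this comparison. Complement C3S, a complement component made in the liver, was saturated on all 12 arrays, so it has only a bound in each group and is left out of the comparisons. Zona pellucida glycoprotein 3, a protein of the egg envelope, had a log2 ratio of -1.52 ± 0.29 (SD, n = 4) after EE2 and -1.52 ± 0.35 (SD, n = 4) in controls, a difference of -0.01 with a 95% confidence interval of -0.57 to 0.56, with 1 control array saturated. Cytochrome b, a mitochondrial subunit of the respiratory chain, had the next smallest p. It measured 0.88 ± 0.17 (SD, n = 4) after EE2 against 1.43 ± 0.33 (SD, n = 4), with no overlap between the groups (exact permutation p = 0.0286) and a limma adjusted p of 0.505. Lamin B1, a protein of the nuclear envelope, differed by -0.18 (SE 0.17), and cyclin B1, which drives entry into mitosis, by -0.09 (SE 0.21). Inhibin, a subunit of gonadal hormones, was well above background on only 3 control, 1 EE2 and 1 mixture arrays and differed by -0.14 (SE 0.16), a value that rests on dim spots. The leukocyte integrin CD18 type 2 differed by 0.11 (SE 0.28) and the taurine transporter by 0.18 (SE 0.26). Pentraxin, an acute phase protein, and alpha amylase, a starch-digesting enzyme of the exocrine pancreas, varied widely between arrays and differed by -1.18 (SE 1.37) and 0.32 (SE 1.04). Pentraxin was well above background on 3 control, 3 EE2 and 4 mixture arrays and saturated on 1 control array, and without control replicate 3 its difference was 0.33. The alpha amylase difference was -0.37 without control replicate 1 and 1.29 without control replicate 2.

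**Figure D1:**
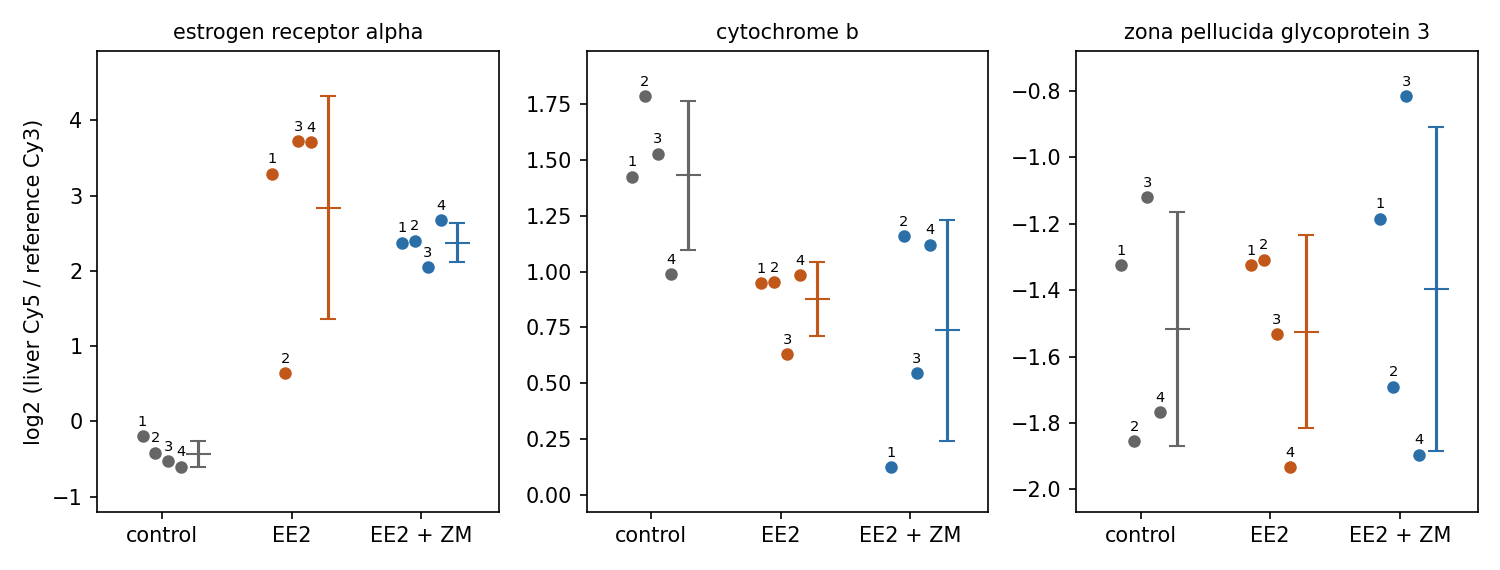
Log2 ratio of liver over reference on each array for estrogen receptor alpha, cytochrome b and zona pellucida glycoprotein 3; each panel has its own vertical scale, points are arrays numbered by replicate, and bars are the mean ± SD of 4 arrays. Estrogen receptor alpha lies between 2.05 and 3.72 on 7 of the 8 exposed arrays and at 0.64 on EE2 replicate 2, above all 4 control arrays.

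Among all tested probes, 1 rose after EE2 at a limma adjusted p under 0.05 and none fell, and 1192 had an unadjusted p under 0.05. The probe that rose, EA_Pp_52388 (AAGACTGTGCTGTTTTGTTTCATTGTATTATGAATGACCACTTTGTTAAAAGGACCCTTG), comes from an expressed sequence contig without a gene name. Its log2 ratio was 4.88 ± 0.27 (SD, n = 4) after EE2 and 2.95 ± 0.37 (SD, n = 4) in controls, 3.81-fold higher (adjusted p = 0.0209) and higher on 4 of 4 slides. Probe EA_Pp_67921 (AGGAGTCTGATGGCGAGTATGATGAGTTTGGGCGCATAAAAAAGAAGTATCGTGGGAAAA), chosen after its values were seen, measured -0.73 ± 0.18 (SD, n = 4) after EE2 against 0.51 ± 0.18 (SD, n = 4) in controls, with an adjusted p of 0.0639. The count of changed probes depends on the processing. The 1 call was lost with Cy5 alone and without control 1, 2 or 3 or EE2 1 or 3, and array quality weights gave 65. It was 12 (8 higher and 4 lower) in the deposited processed log ratios, 3 (1 higher and 2 lower) with median centring, and 7 (5 higher and 2 lower) once outlying local backgrounds were replaced, a repair chosen after seeing the data, under which the adjusted p of EA_Pp_67921 and of EA_Pp_50072 (described below) was 0.0413 each. With slide as a block as well, the 7 became 2, of which 1 was among the 7, and the 12 became 6.

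The second comparison, the mixture of EE2 and ZM against control, asks what the estrogen did in the presence of its antagonist. Estrogen receptor alpha measured 2.38 ± 0.26 (SD, n = 4) in the mixture group against -0.43 ± 0.18 (SD, n = 4) in controls, a 7.02-fold higher level (95% confidence interval 3.06 to 16.1). That value includes mixture replicate 3 at 2.05, an array with a distorted background correction. Once outlying backgrounds were replaced that array was at 3.27. The mixture level was then 9.06-fold and the EE2 level 10.1-fold that of controls. All 4 mixture arrays lay above all 4 controls (exact two-sided permutation p = 0.0286), by 2.57 to 3.28 within the 4 slides. The adjusted p in limma's test was 0.180 over all probes, which does not pass, and 2.6e-04 over the list alone, again an unadjusted p. The same difference had an adjusted p of 0.0011 when only the mixture and control arrays entered the fit, so the spread of the EE2 arrays bears on the failed test. Zona pellucida glycoprotein 3 differed by 0.12 (95% confidence interval -0.44 to 0.68). Cytochrome b was at 0.74 ± 0.50 (SD, n = 4) against 1.43 ± 0.33 (SD, n = 4), with an adjusted p of 0.469. Alpha amylase differed by 1.59 (SE 1.04), pentraxin by -0.80 (SE 1.37), CD18 type 2 by -0.31 (SE 0.28, or -0.14 with SE 0.13 once backgrounds were replaced) and cyclin B1 by -0.13 (SE 0.21). Over the other settings alpha amylase ranged from 0.90 to 2.56 and pentraxin from -1.74 to 0.71. The taurine transporter differed by -0.10 (SE 0.26), inhibin, dim on most exposed arrays, by 0.04 (SE 0.16) and lamin B1 by 0.01 (SE 0.17). None of these passed the test.

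No probe passed a limma adjusted p of 0.05 for the mixture against control, while 1001 had an unadjusted p under 0.05. The unnamed probe EA_Pp_50072 (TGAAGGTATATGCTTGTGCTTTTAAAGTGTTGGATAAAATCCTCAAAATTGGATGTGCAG), chosen after its values were seen, measured 2.95 ± 0.27 (SD, n = 4) in the mixture group, 2.79 ± 0.17 (SD, n = 4) after EE2 and 0.70 ± 0.76 (SD, n = 4) in controls, with 1 mixture array saturated and an adjusted p of 0.0556 for the mixture and 0.0639 for EE2. Probe EA_Pp_65395 (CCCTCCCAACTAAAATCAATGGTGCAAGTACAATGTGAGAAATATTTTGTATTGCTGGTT), also chosen after its values were seen, measured 2.39 ± 0.42 (SD, n = 4), 3.50 ± 0.23 (SD, n = 4) and 3.99 ± 0.19 (SD, n = 4) in the same order, with an adjusted p of 0.0556 for the mixture. The deposited processed log ratios gave 18 changed probes (12 higher and 6 lower). With outlying local backgrounds replaced there were 8 (4 higher and 4 lower), probes EA_Pp_50072, EA_Pp_65395 and EA_Pp_52388 among them at an adjusted p of 0.0298 each (0.111 for EA_Pp_52388 in the planned setting). With slide as a block as well, the 18 became 0, and 8 probes were called with replaced backgrounds, 7 of them the same.

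**Figure D2:**
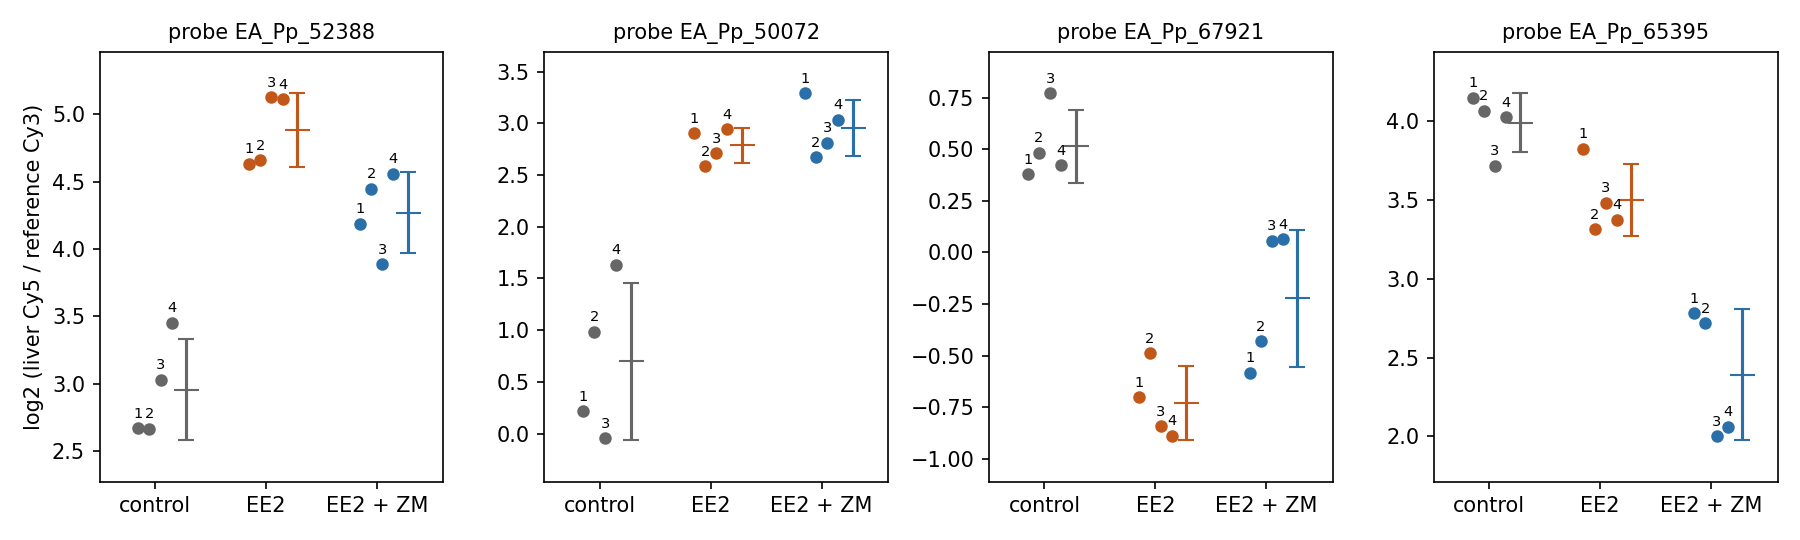
Log2 ratio of liver over reference on each array for 4 probes without a gene name; each panel has its own vertical scale, points are arrays numbered by replicate, and bars are the mean ± SD of 4 arrays. EA_Pp_52388 and EA_Pp_50072 have higher means in both exposed groups than in controls (4.88 and 4.27 against 2.95, and 2.79 and 2.95 against 0.70), and EA_Pp_67921 and EA_Pp_65395 lower means.

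The third comparison, the mixture against EE2, asks what adding ZM changed. Estrogen receptor alpha was at 2.38 ± 0.26 (SD, n = 4) with ZM and 2.84 ± 1.48 (SD, n = 4) without, a difference of -0.46 (95% confidence interval -1.66 to 0.73, limma adjusted p = 0.984, exact permutation p = 0.657). That interval runs from 0.32 to 1.66 times the EE2 level, so with all 4 arrays neither a clear reduction nor an unchanged level was shown. The interval again rests on a spread shared by the 3 groups and may be too narrow. Without EE2 replicate 2, an array left out because of its receptor level, the difference was -1.20 (limma adjusted p = 0.317 over all probes and 5.1e-05 adjusted over the list alone). With backgrounds replaced too it was -0.89 (adjusted p = 0.652 over all probes and 0.0018 adjusted over the list alone), while with all 12 arrays and backgrounds replaced it was -0.16 (SE 0.56), as the receptor level of mixture replicate 3 went from 2.05 to 3.27. The receptor's difference thus depends on both arrays, and it lay between -1.20 and -0.06 over all settings. The p-values from the fits without EE2 replicate 2 are no independent test, because the array was left out for its receptor level. Zona pellucida glycoprotein 3 differed by 0.13 (SE 0.26), cytochrome b by -0.14 (SE 0.24), CD18 type 2 by -0.42 (SE 0.28, or -0.12 with SE 0.13 once backgrounds were replaced) and alpha amylase by 1.27 (SE 1.04). Lamin B1 differed by 0.19 (SE 0.17), inhibin, well above background on 1 array of each group, by 0.18 (SE 0.16), the taurine transporter by -0.27 (SE 0.26), pentraxin by 0.38 (SE 1.37) and cyclin B1 by -0.04 (SE 0.21). None of the named genes passed over all probes. No probe passed a limma adjusted p of 0.05. Of the 12591 probes, 505 had an unadjusted p under 0.05, a share below the 0.05 expected without any difference. Of the 35 splits of these arrays into 4 and 4, 24 gave at least as many. The count was 0 in the deposited processed log ratios and with backgrounds replaced, and 3 when only the 2 groups compared entered the fit.

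The share of the EE2 response retained in the mixture was estimated on probes selected with other arrays. In each of 36 splits, 2 EE2 and 2 control arrays chose the probes and the remaining arrays measured them. The median ratio of the mixture effect to the EE2 effect was 0.689, with a range of -0.081 to 1.34 over splits, and the ratio was above 1 in 6 splits. The median log2 effect on the chosen probes was 0.52 for EE2 and 0.40 for the mixture. With backgrounds replaced the median ratio was 0.646, with a range of 0.084 to 1.30. The retained share was not resolved.

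Across the 12591 probes, the EE2 and the mixture differences from control had a Pearson r of 0.617, an r across probes, which are not independent replicates. All 12 arrays were also simulated without any effect, with the simulated controls shared by both comparisons. These gave a mean r of 0.498, with a range of 0.460 to 0.540 over 100 simulations. The observed r lay above that range. The simulations gave all 3 groups the same spread per probe, estimated with mixture replicate 3 included. That equal spread sets the centre of the range, so unequal spreads could move it. Each probe also had independent noise, so the range may be too narrow. The part of the shared controls is not settled by these simulations. The covariance was 0.0888 against a simulated 0.0548. With the controls split into 2 and 2, so that no array was shared, r was 0.241 on average, between 0.103 and 0.324 over 6 splits. An r from 2 controls per side carries more noise, so the covariances compare better. With split controls the covariance was 0.0445 on average, against 0.0888 with shared controls (0.0496 against 0.0961 with backgrounds replaced). A positive covariance thus remained without a shared array, though every slide held all the groups.

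**Figure D3:**
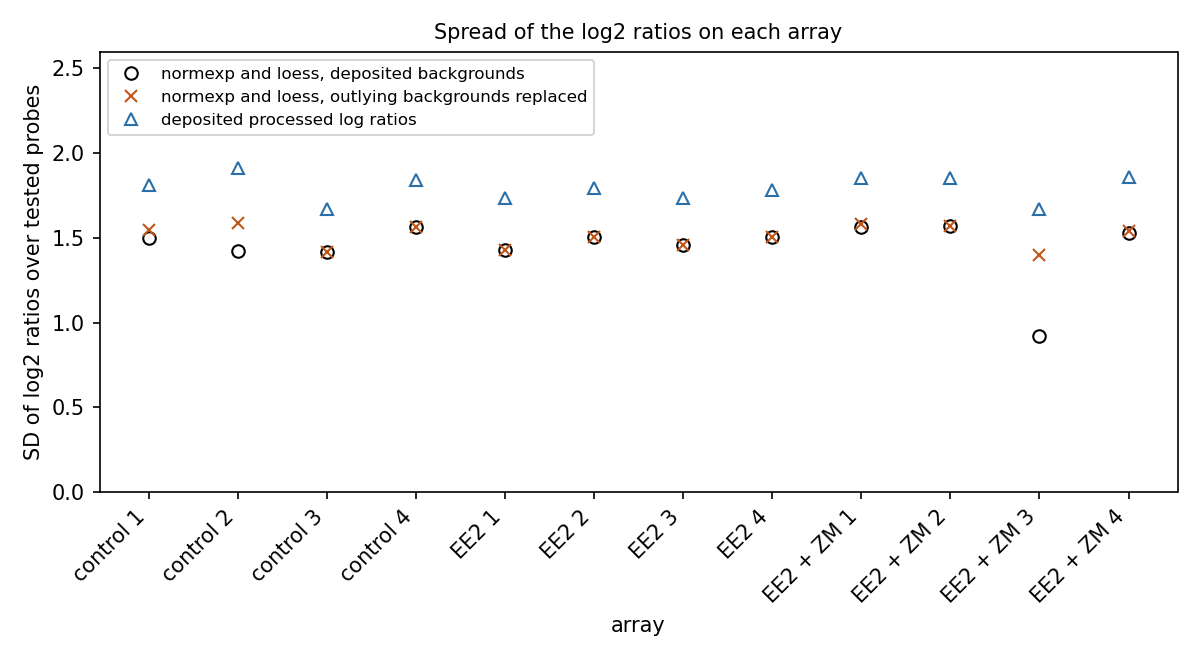
Standard deviation of the log2 ratios over the tested probes for each of the 12 arrays under 3 treatments of the signal (circles, crosses and triangles as in the key). Mixture replicate 3 is at 0.919 with deposited backgrounds, where the other 11 arrays lie between 1.42 and 1.57, and at 1.40 once outlying backgrounds are replaced.

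All 3 comparisons carry the same limit of layout. Each of the 4 slides held 1 array of each group, always at the same position for a group, so position on the slide and group cannot be told apart. A block for the slide cannot change a difference in this layout, only its test. With it, estrogen receptor alpha had adjusted p of 0.167 and 0.251 against control, and the counts of changed probes were again 1, 0 and 0.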

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

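Of 60 groups of 4 arrays examined over named genes, printed probes and array measures, 6 held an array far from the other 3, where chance gives about 1 in 20. The tests of the background and of the array's hybridisation for mixture replicate 3, and the test of a control liver for EE2 replicate 2, were chosen after the results were seen.

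Estrogen receptor alpha was at 0.64 on EE2 replicate 2, far from the 3.29 to 3.72 of the other EE2 arrays and above the -0.60 to -0.20 of the controls. On the 100 probes that best part mixture from control, chosen without any EE2 array, this array scored 0.717 on the log2 scale, where the other EE2 arrays scored 0.945 to 1.37 and left-out controls 0.161 to 0.524. That is above the highest control by more than the SD of the 4 control scores (0.163), though by a narrow margin, and argues against a control liver in place of an EE2 liver. The slope of its log2 ratios on the mean of the other 3 EE2 arrays was 0.980, and the other arrays gave 0.914 to 1.02, which argues against compressed ratios. A weaker response of this sample to the same exposure, or a difference in the exposure itself, may remain, and neither was tested.

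The SD of the log2 ratios on mixture replicate 3 was 0.919, far below the 1.53 to 1.57 of the other mixture arrays. This array had 23 spots with an outlying Cy5 background, up to 43811.5 against a median of 56, and the 10th percentile of its corrected Cy5 signal was 772, against 68.4 after these backgrounds were replaced. After the replacement its SD was 0.987 of the lowest of the other 11 arrays, as an effect of those few backgrounds on the correction would give. In the deposited processed log ratios it was 1.00 of the lowest other array, which argues against weak hybridisation or RNA as the whole cause. A smaller true difference may remain, since the processed SD of 1.67 was itself far from the 1.85 to 1.86 of the other mixture arrays. The lowest other array was control replicate 3, on the same slide and also at 1.67, and EE2 replicate 3 there was at 1.73. The ratio of 1.00 therefore cannot speak to a hybridisation effect shared by that slide.

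CD18 type 2 was at 0.19 on mixture replicate 3, far from 1.42 to 1.60 on the other mixture arrays, and at 1.35 there once backgrounds were replaced. Cytochrome b was at 0.63 on EE2 replicate 3, far from 0.95 to 0.98 on the other EE2 arrays. Cyclin B1 was at -2.71 on control replicate 3, far from -3.37 to -3.27 on the other controls.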

How the results depend on the processing

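The settings with replaced backgrounds, the processed log ratios with slide as a block and maximum likelihood normexp were added after seeing the data; the others were planned. Where no construction is named, the cause was not tested. Counts of changed probes are for EE2 against control, then the mixture against control, with counts at least 2-fold in parentheses; they were 1 (1) and 0 (0). They became 12 (12) and 18 (18) with Agilent processed log ratios and with series matrix values, 6 (6) and 0 (0) with the processed log ratios and slide as a block, 6 (5) and 8 (7) without background subtraction, 4 (4) and 6 (6) with only the 2 groups compared, 2 (2) and 4 (4) with trend and robust, and 65 (42) and 27 (23) with array quality weights, where mixture replicate 3 had a weight of 0.163. Median centring gave 3 (3) for EE2, with a shift of the median mixture minus EE2 difference to 0.10. Cy5 alone gave 0 (0) and 1 (1), Cy5 well above background on all 12 arrays gave 2 (2) for the mixture, and named genes only, with 11 probes tested, gave 1 (1) for the mixture. With local background outliers replaced the counts were 7 (6) and 8 (7). They were 40 (34) and 27 (23) with EE2 array 2 left out as well, and 75 (48) and 23 (19) with array weights as well. The mixture against EE2 gave 3 (3) with only the 2 groups compared and 0 under each other setting that keeps all arrays. Offset 10, maximum likelihood normexp, no filter and the Cy3 filter changed no count, and Aquantile leaves the ratios as they were by construction.

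Leaving out 1 array gave 0 to 11 (0 to 11) for EE2, 0 to 8 (0 to 8) for the mixture and 0 to 1 (0 to 1) between them. EE2 counts were 0 without control 1, 2 or 3 or EE2 1 or 3, and 3 without control 4, 11 without EE2 2, 4 without mixture 1 and 7 without mixture 3. Mixture counts were 8 without EE2 2, 3 without EE2 1 or mixture 1, and 1 without control 3, control 4 or mixture 3. The mixture against EE2 gave 1 without EE2 4 or mixture 1. Gene list members past 0.05 adjusted over the list alone (here the unadjusted limma p) numbered 1 to 2, 1 to 2 and 0 to 1 in the 3 comparisons. The second members, both without control 2, were complement C3S after EE2, which is saturated and so no measured change, and alpha amylase in the mixture. With backgrounds replaced and EE2 array 2 left out, 1 list member, estrogen receptor alpha, against 0, passed between the mixture and EE2. That is no independent test, as the array was left out for its receptor level. The retained share was 0.631 to 0.892 and the correlation of effects 0.546 to 0.675 when 1 array was left out, and neither moved beyond its spread under any setting run. The spread was the SD over splits, 0.322 for the share and 0.082 for the correlation with split controls. With spreads this wide, an unmoved share or correlation shows little about stability. Neither was run under 10 settings: named genes only, only the 2 groups compared, trend and robust, maximum likelihood normexp, and every setting with array weights or a block.

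The replicate number is also the slide, so the 2 blocks are the same fit. The labels do not say that same-numbered samples belong together, and not every pair of residuals correlated over 0.1. Those of same-numbered arrays correlated between -0.18 and 0.15, over 0.1 in 3 of 12 pairs (4 with backgrounds replaced), and in 4 of 12 pairs the array matched its own number best. With the replicate number as a block the counts were 1, 0 and 0, and with backgrounds replaced too they were 2 (2), 8 (7) and 0 (0).

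The estrogen receptor alpha difference kept its sign under all 34 settings, from 2.98 to 4.09 for EE2 and 2.71 to 4.02 for the mixture. It passed 0.05 over the probes tested in 7 and 8 of them (adjusted p from 3.9e-06 to 0.277 and 5.2e-05 to 0.514), and its difference between the mixture and EE2 passed in 0. These settings are not separate tests. Those that passed include the fits without EE2 replicate 2 and the fit of named genes only. They also include both the processed log ratios and the series matrix, which hold nearly the same values. Signs changed, for values near 0, for complement C3S after EE2 with Cy5 alone (0.022, from spots saturated on every array and so no measured change), CD18 type 2 in the mixture without mixture 3 (0.028, from -0.44 when each array was left out in turn), and between the mixture and EE2 for inhibin with backgrounds replaced and EE2 array 2 left out (-0.00557) or array weights (-0.019), and for the taurine transporter with array weights (0.026) and with backgrounds replaced and EE2 array 2 left out (0.017). Signal over background limits the named genes, as 22 of 33 were too dim to test.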

Other observations

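The tests of other groupings for the unadjusted counts with replaced backgrounds, and the simulated overlap of probes, were chosen after the results were seen, and the replacement itself was chosen after seeing the data. Several other patterns across probes and arrays were looked through before those given here were chosen. Some genes varied widely between arrays of the same group. Alpha amylase, the digestive enzyme on the list of exocrine pancreas markers, ranged from -1.79 to 3.34 on the log2 scale over the 12 arrays, from -1.79 to 3.18 in controls, from -1.12 to 2.54 after EE2 and from 0.32 to 3.34 in the mixture group. Pentraxin ranged from -1.65 to 5.74, with its highest value on control replicate 3, and was saturated on 1 control array. With backgrounds replaced, 13 probes split the 12 arrays into 2 levels at least 8-fold apart with at least 3 arrays at each level, a criterion set after seeing the data. The levels followed the groups for 0 of these probes, and for 13 both levels occurred inside at least 1 group.

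With backgrounds replaced, the 7 probes changed by EE2 all differed from control in the same direction in the mixture, and the 8 changed by the mixture did so after EE2. The 2 sets shared 3 probes. The comparisons share their control arrays. In 100 simulations all arrays were drawn without any effect, with simulated controls shared by both comparisons and an equal spread per probe in each group. There the 7 probes with the smallest p had the same direction in 6.63 of 7 cases on average and the 8 in 7.49 of 8. The 2 sets shared 0 to 3 probes (mean 0.88). The common direction and the overlap therefore do not by themselves show a shared effect. The correlation of the 2 sets of differences over all probes, 0.631 with backgrounds replaced, lay above its simulated range of 0.466 to 0.536. That range rests on independent noise per probe and may be too narrow, and its centre rests on an equal spread in the 3 groups.

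For EE2 against control, 6 of 35 splits of the 8 arrays gave at least the 1 changed probe (also 6 at 2-fold), the highest other split giving 2, so chance is not excluded for that count. The 1192 probes with an unadjusted p under 0.05 were exceeded by no other split (1 of 35, highest other 1033), nor were the 7 changed probes with replaced backgrounds (1 of 35, highest other 3), the 1829 unadjusted ones there (1 of 35, highest other 1443) or the 12 in the deposited processed log ratios (1 of 35, highest other 3). A share of 1 in 35 is the smallest these splits can give. They leave the slides out of account and several counts were tried, so chance is not settled for these counts. With slide as a block as well, the 7 became 2, with 1 probe in common, and the 12 became 6, and no splits were run for those counts. For the mixture against control, the planned setting excluded nothing, since all 35 splits reached its count of 0 (also at 2-fold, highest other 1) and 5 of 35 reached 1001 unadjusted probes (highest other 2210). With replaced backgrounds, 2 of 35 reached the 8 changed probes (highest other 21), which does not exclude chance. Only the real split, 1 of 35, reached the 1334 unadjusted ones (highest other 1223) and the 18 in the processed log ratios (highest other 12), with the same limits. With slide as a block 8 probes were called, 7 of them the same, and the 18 became 0.

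The split with 21 changed probes set mixture replicates 1 and 2 and control replicates 1 and 4 against the other 4 arrays, a count above the real 8, as a structure among the arrays that crosses the groups would give. Whether there is one was not tested. For the mixture against EE2, all 35 splits reached 0 changed probes (2-fold too, highest other 2), all 35 with replaced backgrounds (highest other 1) and all 35 in the processed log ratios (highest other 2). Of the 35, 24 reached the 505 unadjusted probes (highest other 1248) and 7 the 831 with replaced backgrounds (highest other 1405). Both highest counts came from the split of slides 1 and 2 against slides 3 and 4. With slide as a block the count of changed probes in this comparison was 0.

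The 83 probes with the highest liver over reference ratio (mean log2 above 3, backgrounds replaced) were looked at for a loss of liver-typical transcripts. Their median difference from control was -0.16 after EE2 and -0.24 in the mixture, and the array medians did not differ beyond their spread (exact permutation p = 0.429 and 0.171), so no loss was shown. The 81 of them that were never saturated gave -0.165 and -0.241, close to the values of all 83, so the saturated spots do not carry these medians. The deposited processed log ratios, with Feature Extraction's own background subtraction and dye normalisation in place of normexp and limma's loess, gave -0.159 and -0.186. They are still dye-normalised, so they cannot test the part of that step. Leaving out 1 control array brought the EE2 value as near to 0 as -0.109. In none of these tests did both exposed groups pass a bound set beforehand, so background correction, dye normalisation, single control arrays and a small true difference cannot be told apart with 4 arrays per group. In the planned setting the 2 medians were -0.11 and -0.44. The 466 probes with the lowest liver over reference ratio had a median of 0.08 after EE2 and -0.21 in the mixture with backgrounds replaced, also not beyond the spread of the arrays (exact permutation p = 0.457 for both), and -0.05 and -0.04 in the planned setting.

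The array also carries 1618 probes whose names mark them as the opposite strand of another probe's contig. In 604 of these pairs only the partner probe had enough liver signal to be tested, in 267 only the opposite-strand one, in 242 both and in 505 neither. Only 4 of the 1618 are exact reverse complements of their partner, so most pairs do not compare strands at the same site.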
